A study of Homo sapiens with 6 samples.

How the data were processed

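RNA was sequenced from HCT-8 cells that had received a control or a PNISR hairpin plasmid, 3 libraries in each group. The deposited table holds whole-number read counts for 60664 Ensembl gene IDs, 60463 of them with a symbol, and these counts were not normalized. HISAT2 2.0.4 and the genome build GRCh38 are listed per the submitters' processing notes. The read counter, the annotation release and the strand setting are not given in the sources used here. Without a strand setting, overlapping and antisense genes cannot be separated, and reads from near-identical copies may be split or dropped. Each column was matched to its library by name, and no column was left out. Total counts ranged from 15049485 to 17977803 per library, and counts of different libraries in a group differed by more than sampling noise, so all 6 were kept as separate replicates.

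Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 16102. Libraries were scaled with TMM factors, and the groups were compared with edgeR 4.0.16 in R 4.3.3 by a robust quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment at 0.05. Standard errors were taken from the fold change and the test statistic. CPM values are TMM-scaled. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over the 30 of 31 lists with at least 5 tested members, beside camera with an estimated correlation and fry. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names PNISR; the 10 highest and 10 lowest genes by fold change among those that passed, had a mean of at least 5 CPM, had a symbol and had groups that did not overlap; and from each list up to 4 members with the smallest adjusted p, or up to 2 with the highest CPM where none passed. Other members named were chosen after their values were seen.

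Positions, exon length, GC content and overlaps came from GENCODE release 29 on GRCh38, which held 99.35% of the tested genes. Some list members are in doubt, noticed after values were seen. ALDOA in the hypoxia and glycolysis list had a mean of 2.19 CPM in shNC beside 4326 CPM for GAPDH, and NDUFV2 in the oxidative phosphorylation list 0.528 CPM beside 244 CPM for NDUFV1, so their counts may be incomplete, and neither passed. SOD2 in the NF-kB list matched no symbol and was not tested. The alternatives were DESeq2 size factors, upper-quartile factors and library totals, no low-count filter or a mean of at least 1 CPM, DESeq2 1.42.0, limma voom, no robust dispersion, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were a correction of each library for GC content and length by loess (span 0.4), that correction with shNC 2 left out, and a fit of 2 libraries per group without shNC 3 and shPNISR 2. On data simulated for shPNISR against shNC with 3 libraries each, over 15870 genes, edgeR recovered 88 of 100 genes changed 2-fold and 58 of 100 changed 1.5-fold, and called 6 unchanged genes. The simulated changes were placed only on genes above a count floor. Genes were drawn independently, and libraries of a group shared the same mean, so recovery and false calls may be worse in the real data. Figures were drawn with matplotlib 3.10.9. Exon and isoform usage was not analysed here.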

Results

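RNA sequencing was carried out on HCT-8 cells, a human colorectal cancer line, that received either a control hairpin plasmid (shNC) or a plasmid expressing a short hairpin RNA against PNISR (shPNISR). The series asks what PNISR does to alternative splicing. The values analysed here are read counts per gene, so the comparison below is of gene expression, and exon or isoform usage was not analysed here. Each group held 3 libraries. Total counts were 17977803, 15526076 and 15049485 in shNC 1 to 3 and 17299847, 16499845 and 15703210 in shPNISR 1 to 3. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

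PNISR, which encodes a serine and arginine rich partner of the splicing protein PNN, was lower in every shPNISR library than in every shNC library. Its level was 56.1 ± 6.32 CPM (counts scaled to library size) in shNC and 22.3 ± 4.74 CPM in shPNISR (mean ± SD, 3 libraries each). The raw counts were 1002, 776 and 943 in shNC and 313, 333 and 450 in shPNISR. The log2 fold change was -1.33 ± 0.15 (SE), which leaves 39.7% of the shNC level (edgeR quasi-likelihood test, two-sided, Benjamini-Hochberg adjusted p = 8.73e-05). PNISR (ENSG00000132424) lies on the minus strand of chromosome 6 at 99398051 to 99425331 in GRCh38 and overlaps the antisense gene AL513550.1. The strand setting of the counting is not given in the sources used here, so reads of the antisense gene cannot be separated from those of PNISR.

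**Figure D1:**
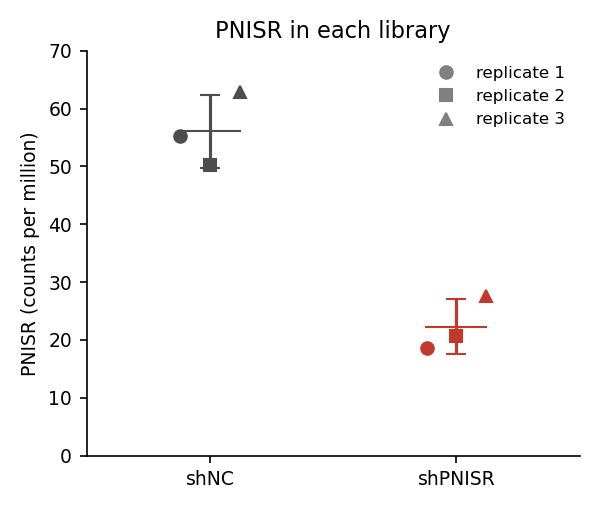
PNISR in CPM (vertical axis) in each of the 3 shNC and 3 shPNISR libraries; the horizontal line is the group mean and the bar its SD. The shPNISR libraries lie between 18.5 and 27.6 CPM and the shNC libraries between 50.2 and 62.8 CPM.

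The comparison of shPNISR with shNC asks which genes respond when PNISR is lowered. SPARC, a secreted matrix glycoprotein, had the largest increase among the genes named by the fixed rule, from 0.849 ± 0.0800 to 9.98 ± 1.25 CPM (log2 fold change 3.55 ± 0.25 SE). BMP2, a secreted growth factor of the TGF-beta family, rose from 3.71 ± 0.336 to 12.2 ± 0.242 CPM. CDH17, an intestinal cadherin, rose from 17.6 ± 2.97 to 44.1 ± 2.26 CPM, and AREG, a ligand of the EGF receptor, rose from 27.3 ± 7.02 to 67.7 ± 9.65 CPM. LTB, a cytokine of the TNF family, fell from 27.6 ± 4.83 to 8.99 ± 1.54 CPM (log2 fold change -1.62 ± 0.17), and POF1B, an epithelial actin-binding protein, fell from 7.97 ± 0.330 to 2.41 ± 0.415 CPM.

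Of 16102 tested genes, 371 were higher and 134 lower with shPNISR by edgeR's quasi-likelihood test at an adjusted p of 0.05. At least 2-fold differences accounted for 150 of the higher and 21 of the lower genes. At an unadjusted p under 0.05 there were 2862 genes. The groups did not overlap in 504 of the 505 called genes and in 21.1% of all tested genes, against 10% by chance for 3 libraries against 3. Besides the genes above, the 10 highest included DUSP13 (1.80 ± 0.25 on the log2 scale), FABP3 (1.61 ± 0.23), IFITM1 (1.44 ± 0.24), L1CAM (1.41 ± 0.24), DDC (1.39 ± 0.22) and RNASE1 (1.64 ± 0.38). Besides PNISR, LTB and POF1B, the 10 lowest were HSPA1A (-1.30 ± 0.33), ARHGEF6 (-1.19 ± 0.22), PCDH10 (-1.06 ± 0.12), CDX1 (-1.06 ± 0.21), SHISA2 (-1.05 ± 0.17), SNAI2 (-1.03 ± 0.17) and FBXO28 (-0.96 ± 0.13). Adjusted p in these 20 genes ran from 3.24e-07 for SPARC to 0.0499 for HSPA1A. SPARC, DDC and L1CAM overlap antisense genes and IFITM1 overlaps IFITM2, so their counts may be shared in part.

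The calls depended on single libraries. Leaving out shNC 1 gave 153 higher and 46 lower genes, and leaving out shNC 2 gave 1284 higher and 746 lower, with 501 of the 505 calls shared. Without shNC 3 there were 336 higher and 221 lower genes. Leaving out shPNISR 1, 2 or 3 gave 133, 217 or 177 higher and 30, 59 or 73 lower genes. The shNC 2 library lay between the groups on the first principal component (scores -22.5, 2.39 and -17.9 for shNC 1 to 3 and 14.9, 16.0 and 7.18 for shPNISR 1 to 3, 51.6% of the variance). Of the 18 alternatives, 6 ended the call of RNASE1 (without shNC 3 or any 1 shPNISR library, after a correction for GC content and length, and with 2 libraries per group), and 2 that of CDX1 (without shPNISR 1 or 3). That of HSPA1A ended in 8: without shNC 1, shNC 2, shPNISR 1 or shPNISR 3, with each of the 3 other scalings, and at a mean of at least 1 CPM.

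**Figure D2:**
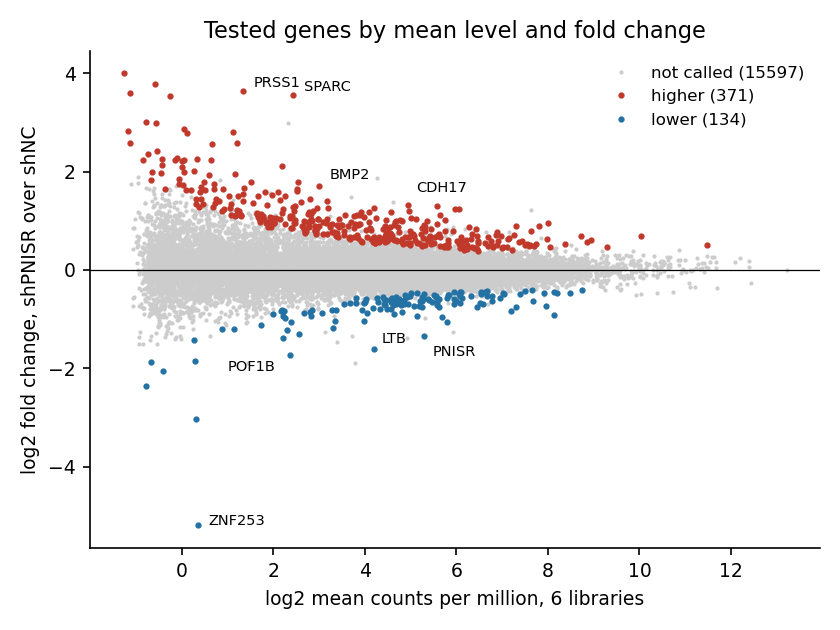
Log2 fold change of shPNISR over shNC (vertical axis) against the log2 mean CPM over 6 libraries (horizontal axis) for each tested gene; red points are the 371 higher genes and blue points the 134 lower genes at an adjusted p of 0.05. PRSS1 and ZNF253 were chosen for a label after their values were seen.

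**Figure D3:**
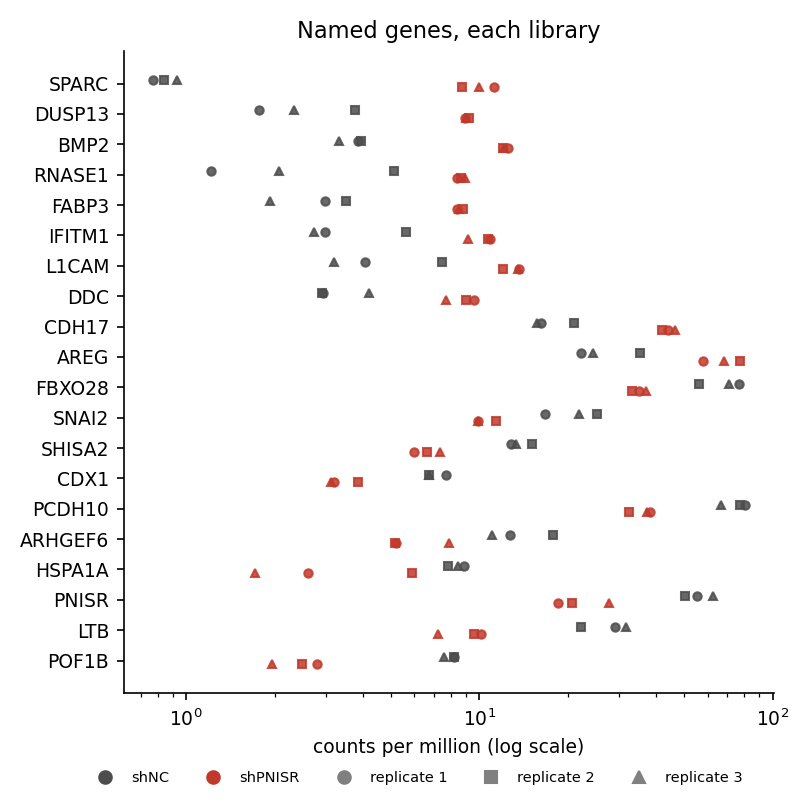
CPM on a log axis in each of the 6 libraries for the 10 highest and 10 lowest named genes; colour gives the group and the marker the replicate number. SPARC lies between 0.773 and 0.932 CPM in shNC and between 8.74 and 11.3 CPM in shPNISR.

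Mesenchymal and invasion genes formed the list with the most called members. Of 26 tested members 11 rose, 1 fell and 14 did not pass, and 16 rose and 1 fell when adjusted over the list alone. Those that rose included SPARC, TGFBI (1.26 ± 0.15), L1CAM, PLAU, CD44, TGFB1, TNC, PLAUR and MMP7, which encode matrix and adhesion proteins, a growth factor, and proteases or a protease receptor. SNAI2, a transcription factor of the epithelial to mesenchymal transition, fell. By camera with a preset correlation of 0.01 the list was higher (adjusted p = 2.62e-07, and adjusted p = 0.64 with an estimated correlation). Its median lay 0.81 above the mean of shNC 1 and shNC 3 in shPNISR and 0.47 above it in shNC 2, and 16 members rose without shNC 2. Median shifts of the other lists are given from that same mean, while camera compared all 3 shNC libraries.

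Of 27 tested members of the list of epithelial adhesion genes and keratins, 4 rose and none fell (8 rose and 1 fell when adjusted over the list alone). They were CEACAM6 (2.23 ± 0.35), CEACAM1 (0.88 ± 0.17), KRT19 (0.61 ± 0.15) and CLDN7 (0.45 ± 0.12), of which the CEACAM genes are close paralogs that can share reads. The list was higher by camera (adjusted p = 0.0035, and adjusted p = 0.64 with an estimated correlation). Its median shift from the mean of shNC 1 and shNC 3 was 0.27 in shPNISR and 0.13 in shNC 2, and 8 members rose without shNC 2. Leaving out shNC 1 or any 1 shPNISR library ended the calls of KRT19 and CLDN7, and leaving out shNC 3 or scaling by library totals ended that of CLDN7. The correction for GC content and length ended both (0.42, adjusted p = 0.0758, for KRT19 and 0.28, adjusted p = 0.108, for CLDN7), and in all 6 and 10 of the 18 alternatives did. The intestinal differentiation list had 13 tested members, of which 3 rose and 1 fell (4 and 1 when adjusted over the list alone). The alkaline phosphatases ALPI (1.59 ± 0.26) and ALPG (1.16 ± 0.30), paralogs that may share reads, and TFF1 (1.12 ± 0.29), a mucosal peptide, rose. CDX1, a transcription factor of intestinal identity, fell. The list was higher by camera (adjusted p = 0.045, and adjusted p = 0.64 with an estimated correlation), with a median shift of 0.28 in shPNISR and 0.03 in shNC 2 and 3 members higher and 1 lower without shNC 2. Its call ended without shNC 3 or any 1 shPNISR library, with upper-quartile factors, with no low-count filter, and after a correction for GC content and length chosen after seeing the data (adjusted p = 0.119, range over alternatives 0.013 to 0.64). The calls of ALPG and TFF1 ended without shNC 1 or any 1 shPNISR library, and that of ALPG also without shNC 3; 9 of the 18 alternatives ended each, among them library totals and the correction for GC content and length.

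Among interferon-stimulated genes, 5 of 23 tested members rose and none fell (11 rose when adjusted over the list alone). They were IFITM1, ISG15 (0.74 ± 0.15), IFITM3 (0.58 ± 0.12), OASL (1.00 ± 0.22) and IFI27, and 19 members had a fitted value above 0. The list was higher by camera (adjusted p = 5.12e-06, and adjusted p = 0.64 with an estimated correlation). Its median shift from the mean of shNC 1 and shNC 3 was 0.54 in shPNISR and 0.34 in shNC 2, and 12 members rose without shNC 2. The calls of ISG15, IFITM3 and OASL ended without shPNISR 1, that of IFITM3 also without shPNISR 2 and that of OASL also without shNC 1. After the correction for GC content and length ISG15 was at 0.48 and did not pass (adjusted p = 0.0568). Of 33 tested hypoxia and glycolysis genes, 3 rose and none fell (5 when adjusted over the list alone), and 32 had a fitted value above 0. These were CA12, a carbonic anhydrase (0.98 ± 0.14), SLC16A3, a lactate transporter (0.68 ± 0.13), and PFKP, a phosphofructokinase (0.59 ± 0.14). The list was higher by camera (adjusted p = 1.75e-07, and adjusted p = 0.64 with an estimated correlation). The median log2 fold change with all 6 libraries was 0.38. From the mean of shNC 1 and shNC 3 the median shift was 0.67 in shPNISR and 0.68 in shNC 2, and 24 members rose without shNC 2. Of 26 tested AP-1 and immediate early genes, 2 rose and none fell (5 when adjusted over the list alone), namely ETV4 (0.72 ± 0.12) and SPRY4 (0.57 ± 0.15), both targets of ERK signalling. The list was higher by camera (adjusted p = 0.000117, and adjusted p = 0.64 with an estimated correlation). The median log2 fold change with all 6 libraries was 0.32. From the mean of shNC 1 and shNC 3 the median shift was 0.53 in shPNISR and 0.47 in shNC 2, and 18 members rose without shNC 2. The call of PFKP ended without shNC 1, shPNISR 1 or shPNISR 3, and that of SPRY4 in 8 of the 18 alternatives, among them library totals and leaving out any 1 library but shNC 2.

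Of the 7 lists of RNA processing genes, 3 were called lower by camera, with few single genes called. All 29 tested RS-domain and detained-intron genes had a fitted value below 0, and 2 fell: TIA1 (-0.54 ± 0.14), an RNA-binding splicing regulator, and NKTR (-0.63 ± 0.17), a cyclophilin with an arginine and serine rich tail. Adjusted over the list alone the count was also 2, and camera gave an adjusted p = 7.05e-06 (adjusted p = 0.64 with an estimated correlation). The call of TIA1 ended without shNC 1, shNC 3 or any 1 shPNISR library, and that of NKTR without shNC 1, shPNISR 1 or shPNISR 2. Both also ended with upper-quartile factors, library totals, a mean of at least 1 CPM, no robust dispersion and the correction for GC content and length (TIA1 -0.39, adjusted p = 0.0655; NKTR -0.40, adjusted p = 0.087), and in all 12 and 9 of the 18 alternatives ended them. None of the 14 SR splicing factors passed, of which 13 had a fitted value below 0, nor did any of the 27 hnRNP regulators, of which 25 did; no member of either list passed when adjusted over the list alone. SRSF3 was at 572 ± 131 CPM in shNC and 495 ± 36.9 CPM in shPNISR, and HNRNPA1 at 2101 ± 115 and 2030 ± 178 CPM. Camera gave an adjusted p = 0.00793 for the SR list and 0.0113 for the hnRNP list (adjusted p = 0.64 for both with an estimated correlation). Median shifts of the RS-domain, SR and hnRNP lists from the mean of shNC 1 and shNC 3 were -0.41, -0.38 and -0.17 in shPNISR. In shNC 2 they were -0.39, -0.58 and -0.12. Without shNC 2, 14, 9 and 3 of their members fell, SRSF3 among them (adjusted p = 0.04). The SR and hnRNP calls ended without shNC 3, without shPNISR 3, and after the correction for GC content and length (adjusted p = 0.167 and 0.269), though with shNC 2 also left out the SR call held (0.000919) and the hnRNP call did not (0.0884).

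The PNN partners and exon junction complex, the core spliceosome, the nonsense-mediated decay factors and the snoRNA host genes were not called, with adjusted camera p of 0.155, 0.141, 0.146 and 0.141 and no member past the test in either adjustment. Among them SRRM2 was at 660 ± 136 CPM in shNC and 516 ± 121 CPM in shPNISR, and PRPF8 at 808 ± 151 and 728 ± 145 CPM. SRRM2 fell without shNC 3 (adjusted p = 0.0408). Leaving out shNC 2 gave lower calls for the PNN and the snoRNA host lists (adjusted p = 0.0392 for both), shPNISR 1 for the core spliceosome (0.0394), and shPNISR 2 for the core spliceosome and the snoRNA hosts (0.038 and 0.015). Of 33 tested S phase and DNA replication genes, CDC6, which loads the replicative helicase, fell (-0.69 ± 0.12) and no other passed (2 fell when adjusted over the list alone). The list was lower by camera (adjusted p = 0.00523, and adjusted p = 0.64 with an estimated correlation). The median shift of this list from the mean of shNC 1 and shNC 3 was -0.14 in shPNISR and -0.11 in shNC 2. Without shNC 2, 4 fell and 1 rose. Its call and that of CDC6 ended without shPNISR 3. None of the 13 mitochondrially encoded mRNAs passed, 6 fell when adjusted over the list alone, and all 13 had a fitted value below 0. The list was lower by camera (adjusted p = 0.000259, and adjusted p = 0.64 with an estimated correlation). The median log2 fold change with all 6 libraries was -0.35. From the mean of shNC 1 and shNC 3 the median shift was -0.47 in shPNISR and -0.46 in shNC 2, and 9 members fell without shNC 2. Mitochondrial transcripts took 2.23 ± 0.378% of counts in shNC and 1.77 ± 0.208% in shPNISR (exact permutation test, two-sided, p = 0.2, where 0.1 is the smallest that 3 against 3 allows).

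The remaining lists were not called by camera. HSPA1B (-0.46 ± 0.11) and HSPA1A fell among 18 heat shock genes, 2 when adjusted over the list alone (list adjusted p = 0.19); the pair are near-identical copies, so their counts are uncertain. TRIB3 (0.47 ± 0.12) rose among 30 ATF4 and unfolded protein response genes (2 over the list alone, list adjusted p = 0.0544), NT5E (1.08 ± 0.16) among 15 YAP and TEAD targets (2 over the list alone, 0.934) and CD44 (0.87 ± 0.16) among 20 Wnt target and stem cell genes (1 rose and 1 fell over the list alone, 0.96). For both of the last lists the median was below 0 and the mean and camera direction above it. UQCRC2 (-0.40 ± 0.11) fell among 40 nuclear genes of oxidative phosphorylation (none over the list alone, 0.934). The calls of HSPA1B, TRIB3 and UQCRC2 ended without shNC 1, shNC 3 or any 1 shPNISR library, and in all in 6, 11 and 9 of the 18 alternatives. For TRIB3 these include library totals, no robust dispersion and the correction for GC content and length (0.29, adjusted p = 0.122), and for UQCRC2 upper-quartile factors and no robust dispersion. No member passed in the lists of G2 and mitosis (adjusted p = 0.146), p53 targets (0.248), apoptosis (0.319), NF-kB targets (0.13), cholesterol synthesis (0.388), fatty acid synthesis (0.81), ribosomal proteins (0.143) and histones (0.311). Adjusted over the list alone, 1 apoptosis gene and 1 NF-kB target fell. CDKN1A, a p53 target, was at 153 ± 19.9 CPM in shNC and 192 ± 12.3 CPM in shPNISR, and rose without shNC 2 (adjusted p = 0.0153). Leaving out 1 library made further list calls: heat shock lower without shNC 2 or shPNISR 2 (adjusted p = 0.015 and 0.038), NF-kB targets lower without shNC 2 or shPNISR 1 (0.0295 and 0.0394), ATF4 and unfolded protein response higher without shNC 1, shNC 3 or shPNISR 3 (0.0437, 0.041 and 0.0253), which with other changes of setting makes 8 of its 18 alternatives (as low as 0.0147, with limma voom), and ribosomal proteins higher without shNC 3 or shPNISR 3 (0.0451 and 0.000425).

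Fibroblast markers had 8 tested members and leukocyte markers 6 (adjusted p = 0.418 and 0.155), and endothelial markers only 3, too few for the list test. COL1A1 was at 16.2 ± 3.60 CPM in shNC and 23.1 ± 2.68 CPM in shPNISR and FBN1 at 16.8 ± 5.14 and 11.4 ± 3.21 CPM, and neither passed. FBN1 fell without shNC 3 (adjusted p = 0.00593), and with no low-count filter FBN1 fell (adjusted p = 0.0329) and COL1A1 rose (adjusted p = 0.0422). LYZ fell from 1.21 ± 0.287 to 0.287 ± 0.217 CPM, a call that ended without any 1 shPNISR library, with library totals, with DESeq2 and with 2 libraries per group. Adjusted over the list alone, 1 fibroblast marker rose, and 2 leukocyte markers rose and 1 fell. With no low-count filter the leukocyte list was called higher (adjusted p = 0.005, range over alternatives 0.005 to 0.64). Without shNC 2, 3 of the 8 fibroblast markers rose, COL1A1 among them, and the list was higher (adjusted p = 0.0392). The fibroblast median lay 0.37 above the mean of shNC 1 and shNC 3 in shPNISR and 0.50 above it in shNC 2. By fry, which tests whether a list's genes move on balance 1 way, 0 of the 30 lists were called and 6 had an unadjusted p under 0.05. In either direction fry called 11, but these were not the 11 that camera called. Both called the mesenchymal, epithelial, intestinal differentiation and interferon lists. Only fry called the p53, apoptosis, ATF4, Wnt, YAP, leukocyte and histone lists. Only camera called the hypoxia, AP-1, RS-domain, SR, hnRNP, S phase and mitochondrial lists. With an estimated correlation camera called 0 lists, and 1, the interferon list, had an unadjusted p under 0.05 (0.0304). The adjustment gave the same 0.64 to each of the 11 lists called at the preset correlation, but their unadjusted p differed. It was 0.0816, 0.101 and 0.109 for the intestinal differentiation, epithelial and mesenchymal lists, and 0.235 to 0.341 for the rest.

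**Figure D4:**
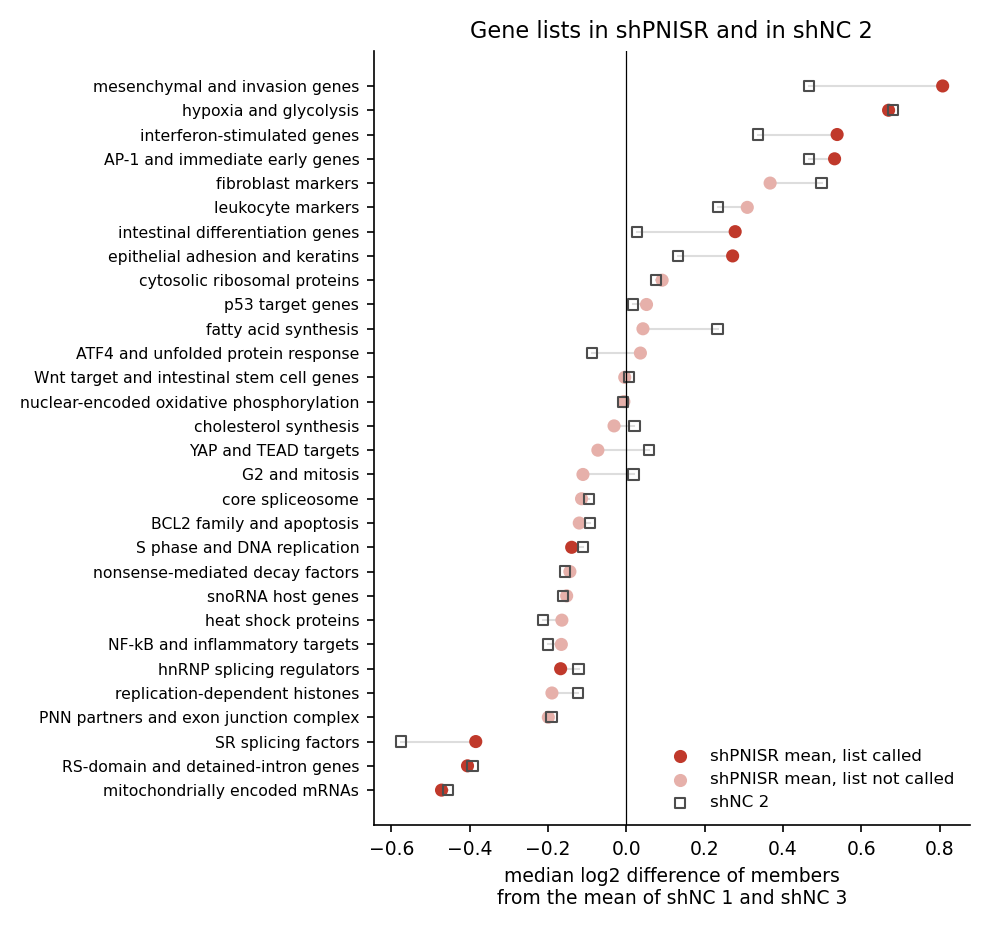
Median log2 difference of each list's tested members from the mean of shNC 1 and shNC 3 (horizontal axis) in the mean of the 3 shPNISR libraries (circles, dark red where camera called the list) and in shNC 2 (squares). In shNC 2 the hypoxia and glycolysis list lies at 0.68 and the mitochondrially encoded list at -0.46, beside 0.67 and -0.47 in shPNISR.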

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

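The corrections for GC content and length and the fit of 2 libraries per group were chosen after seeing the data; the other alternatives were planned. PNISR stayed lower and called in all 18 alternatives (log2 fold change -1.52 to -1.13, adjusted p up to 0.00258). Over the omissions of 1 library it ran from -1.52 to -1.21, with 133 to 1284 higher genes, 30 to 746 lower, 76 to 436 higher and 8 to 64 lower at least 2-fold, and 9 to 16 lists. Library totals gave 71 lower genes, no low-count filter 642 higher, 354 lower and 34 lower at least 2-fold, and DESeq2 214 lower. Fold changes followed GC content (Spearman 0.464). The GC and length correction gave 330 higher and 176 lower genes, with 375 of the 505 calls shared, and with shNC 2 left out gave 1278 and 1191 genes, 340 and 81 at least 2-fold; 2 libraries per group gave 185 and 63, with 86 higher at least 2-fold. Camera with an estimated correlation and fry each called 0 lists (1 and 6 at an unadjusted p under 0.05). Same-numbered libraries did not correlate more than others (0.181, -0.159 and -0.262, against 0.574 for shNC 3 with shPNISR 2), so the replicate block, with 390 higher and 118 lower genes, 438 shared, is given only here; it ended the calls of CLDN7, SPRY4, TRIB3 and UQCRC2 and called the ATF4 list higher (adjusted p = 0.0488). Fold changes that were called in neither fit changed sign. With upper-quartile factors TPX2 was 0.0170. With the GC and length correction HNRNPA2B1 was 0.0499, HNRNPA1 0.0273, SNRNP200 0.0453, GSPT1 0.0176, LCN2 -0.159, RPS2 -0.0869 and H1-2 -0.118, and with shNC 2 also left out HNRNPA2B1 was 0.0243, HNRNPA1 0.0748, PRPF8 0.0084, SNRNP200 0.123, TPX2 0.0350, LCN2 -0.121, RPS2 -0.0495 and H1-2 -0.174. With 2 libraries per group LCN2 was -0.0900, RPS2 -0.0183 and H2BC12 0.0415. By contrast, edgeR called H2BC12 lower after the GC and length correction with shNC 2 left out (-0.3615, adjusted p = 0.0155). Omitting 1 library gave ranges of -0.0216 to 0.144 for SRSF9, -0.120 to 0.0103 for HNRNPA1, -0.193 to 0.0847 for SNRNP200, -0.0039 to 0.136 for SNHG29, -0.0510 to 0.0604 for TPX2, -0.0921 to 0.140 for LCN2, -0.0861 to 0.0589 for FDPS, -0.220 to 0.0566 for FASN, -0.0200 to 0.118 for RPS2 and -0.162 to 0.0601 for H2BC12. Lists that changed direction are given by adjusted p. Oxidative phosphorylation had 0.971 with no low-count filter, and Wnt targets 0.842 at a mean of at least 1 CPM. With the GC and length correction fatty acid synthesis had 0.717, oxidative phosphorylation 0.984, Wnt targets 0.615 and YAP targets 0.76; with shNC 2 also left out they had 0.325, 0.796, 0.258 and 0.592. With 2 libraries per group oxidative phosphorylation had 0.851, Wnt targets 0.997, and YAP targets and fibroblast markers 0.936 each. Omitting 1 library gave 0.309 to 0.81 for fatty acid synthesis, 0.144 to 0.931 for oxidative phosphorylation, 0.000425 to 0.912 for ribosomal proteins, 0.691 to 0.876 for Wnt targets, 0.567 to 0.992 for YAP targets and 0.0392 to 0.869 for fibroblast markers. These ranges cover all omissions, also those that kept the direction. The low ends for ribosomal proteins and fibroblast markers kept it. Their direction changed at 0.36 (without shPNISR 2) and 0.869 (without shNC 3). After the GC and length correction NF-kB targets were called lower (0.0107, range over alternatives 0.00349 to 0.657). Omissions use fewer libraries; otherwise the cause was not tested. At this depth edgeR recovered 58 of 100 genes simulated with a 1.5-fold change, so changes of that size can be missed. The simulation held no displaced library such as shNC 2, so more may be missed in the real data.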

Other observations

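Symbol families were formed after the main results were seen, from the letters before the first digit (281 with at least 8 tested members). A family can therefore hold antisense transcripts and other entries that share the root. Of 10 tested genes with the galectin root LGALS, 7 rose and none fell (6 rose after the correction for GC content and length). Among them were LGALS1 (1.24 on the log2 scale) and LGALS3 (0.76), which encode sugar-binding proteins. Camera gave this family an adjusted p = 1.08e-08 (adjusted p = 0.93 with an estimated correlation). The family median lay 0.99 above the mean of shNC 1 and shNC 3 in shPNISR and 0.42 above it in shNC 2. Of 10 genes with the AKR root 3 rose, including the aldo-keto reductases AKR1B10 (0.90) and AKR1C1 (1.05). Of 13 genes with the annexin root ANXA 3 rose (camera adjusted p = 0.00134 for AKR and 0.0159 for ANXA, and 0.93 for both with an estimated correlation). The AKR1C genes are close paralogs that can share reads. Of 13 genes with the HOXA root HOXA5 (-0.73) and HOXA9 (-0.71) fell (camera adjusted p = 0.00781, and 0.93 with an estimated correlation). The family median was -0.52 in shPNISR and -0.45 in shNC 2. Of 471 zinc finger genes with the ZNF root 6 fell and 1 rose (11 and 0 after the correction for GC content and length), and 374 had a fitted value below 0 (adjusted p = 2.48e-08, and 0.93 with an estimated correlation). In all 21 families were called, 12 after the correction for GC content and length, and 0 with an estimated correlation.

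The tests in the next 3 paragraphs that weigh an explanation were chosen after the pattern was seen, the mixture and list tests in part after earlier results of the same kind; the list calls by camera and the count over splits of the libraries were planned. The shNC 2 library lay towards the shPNISR libraries. Of the 2030 genes called without it, 2007 were also tested with all 6 libraries. Over these its median position was 0.657 on a scale from 0 (the other shNC libraries) to 1 (shPNISR). A trend with GC content and length would remove this, but the median stayed at 0.667 once the trend was taken out (quartiles 0.298 and 1.01). Mixing with shPNISR RNA or cells needs 1 share for all genes; with the dispersion doubled and at the share that fits best, 3.69% of the 2007 genes lay beyond their range on the larger side, against 3.29% of 548 in shNC 3 and 3.08% of 195 in shNC 1 (exact binomial p = 0.000835, 0.149 and 0.362, where the numbers of genes differ). Among genes at least 2-fold apart it was 6.71% of 477 (exact binomial p = 7.12e-07) and at least 4-fold apart 16.2% of 68 (exact binomial p = 9.81e-07), against at most 3.88% and 4.17% in the other libraries. These binomial p-values treat the genes of 1 library as independent, which they are not. The libraries that set the range also chose the genes. SPARC had 13 counts in shNC 2 beside 14 and 14 in the other shNC libraries and 141 to 190 in shPNISR. For this gene that goes against a mixture at a share such as 0.45. PRSS1, with 3 counts beside 8 and 7 (67 to 91 in shPNISR), and IGFBPL1, with 8 beside 13 and 11 (55 to 72), did not shift either. Other genes this far apart did: DES had 44 counts beside 18 and 20 (99 to 142 in shPNISR). ZNF702P had 18 beside 54 and 37 (1 to 7 in shPNISR). These genes were picked after their values were seen, so they do not settle it for the set. They were also called with shNC 2 in its group, which favours genes that did not shift. Among the 68 genes called without it, the linear position had quartiles of 0.038 and 0.711, so both kinds occurred. Over all the genes a mixture cannot be told apart from a change in the cells. The percents beyond range of the 3 shNC libraries were close, and the doubled dispersion was chosen after the values were seen. At the fitted dispersion shNC 1 to 3 had 11.28%, 7.92% and 11.5% over all the genes. They had 11.63%, 11.11% and 3.87% at least 2-fold apart, and 3.33%, 17.65% and 6.06% at least 4-fold apart. The 2 other tests left it open. The linear position was 0.312 for genes at least 4-fold apart against 0.659 for those under 2-fold, with overlapping quartiles. At the best share of 0.45 the counts of 20.96% of 477 genes lay outside their range, against 4.56% in a simulated mixture. The simulated counts were drawn at the dispersion that sets the range, so their low percent is no yardstick for real libraries.

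Of 7 lists of RNA processing genes 3 were called lower, the RS-domain, SR and hnRNP lists (adjusted p = 0.64 for each with an estimated correlation). For the RS-domain list the call by camera at the preset correlation held after the correction for GC content and length (adjusted p = 0.00489, range over alternatives 5.31e-09 to 0.64). Its median shrank from -0.26 (quartiles -0.32 and -0.24) to -0.14 (-0.25 and -0.11) and 0 members then passed edgeR's test. The estimated correlation of this list was 0.53, and the corrected values were tested only at the preset 0.01. Whether the trend was the whole cause therefore cannot be told. For the hnRNP list that trend may account for the call, which ended after the correction with all libraries (adjusted p = 0.269) and without shNC 2 (0.0884) because the shift shrank, from a median of -0.12 (quartiles -0.21 and -0.06) to -0.06 (-0.13 and -0.01). For the SR list it cannot be told apart from other causes: the call ended with all libraries (adjusted p = 0.167, median -0.29 with quartiles -0.33 and -0.20 to -0.13 with -0.23 and -0.05) but held without shNC 2 (0.000919). The change that sets shNC 2 apart stays open for all 70 members: with separate baselines the shift in shNC 2 was 0.798 (bootstrap 0.612 to 0.974) and 1.13 (0.857 to 1.63) times that in shPNISR, and the shifts correlated across genes, which are not independent replicates, at 0.62 and 0.59. The shift in shNC 2 came with PNISR at 50.2 CPM, beside 55.3 and 62.8 in shNC 1 and shNC 3 and 18.5 to 27.6 in shPNISR. A shift of this size was thus seen in 1 library with PNISR well above the shPNISR level. An effect of the PNISR hairpin stays open and was not tested apart from the change in shNC 2.

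The genes at least 4-fold apart numbered 33, of which 29 were higher and 4 lower. ZNF253 had counts of 55, 30 and 37 in shNC and 0, 2 and 1 in shPNISR, PRSS1 8, 3 and 7 against 67, 74 and 91, and the neighbouring cancer-testis genes MAGEA12 and CSAG1 both rose; these genes were chosen after their values were seen. For 32 of the genes, neighbours within 5 Mb were tested, with other genes at least 4-fold apart left out. These neighbours moved the same way by a median of 0.0162 (upper quartile 0.0353, largest 0.141), on the log2 scale. This goes against a gain or loss of a region of that size. A smaller gain or loss, for example of MAGEA12 and CSAG1 together, could not be seen this way and stays open. The PNISR hairpin and a difference between cell populations that arose in culture stay open, and neither was tested.

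The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 505 called genes and 171 at least 2-fold apart, and the highest other split gave 0 of each, so 1 of the 10 splits reached the real count in both. For gene lists 3 of the 10 splits called as many as the real 11, and the highest other called 19. The other splits that did so, with 16 and 19 lists, set shNC 1 and shNC 3 with 1 shPNISR library against shNC 2 and the remaining shPNISR libraries, which points to a structure of the libraries with shNC 2 on the shPNISR side.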
